A study of Mus musculus with 6 samples.

How the data were processed

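Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open DNA and inserts sequencing adapters, in E14TG2a mouse embryonic stem cells. This line is male. Per the labels, the cells grew in medium with 15% serum, 1000 U/ml LIF, 1 µM PD0325901 (a MEK inhibitor) and 3 µM CHIR99021 (a GSK3 inhibitor), and 10 µl of spike-in nuclei was mixed with the cells before transposition. The 6 libraries fall into 3 genotypes of 2 libraries each: wild type (WT), Alkbh5 knockout (KO) and Alkbh5 del-cIDR, an allele that lacks a part called cIDR, where IDR stands for intrinsically disordered region in the series title. ALKBH5 is an RNA demethylase that removes N6-methyladenosine. Groups and replicate numbers come from the sample titles. Nothing in the labels says that the replicates are separate cultures, so the spread between them may be technical. No p value given here measures the spread between libraries, since the tests count regions or shuffle bins along a chromosome.

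The authors deposited 1 list of peaks per library, without pooling replicates. Per the submitters' processing notes, fastp, BWA, SAMtools, Picard, MACS2 and featureCounts were used and the genome build was GRCm39; their versions and settings are not given in the sources used here. Whether reads were shifted to the transposase cut site is not given either. The deposited fold of a peak is a ratio of the tag pileup at the summit to the local background. The deposited significance of a peak is given as −log10 of its p and of its q, and no list holds a peak with a q above 0.05. The score column deposited by the authors equals 10 times the −log10 q rounded down in at least 99.9% of the peaks of each list. These values belong to each peak in its own list; they were used to rank or filter peaks within that list. Heights solved from them were also scaled within each list and then compared between genotypes by chromosome, bin and segment, and no test of single regions between lists is reported. Peaks on the sequence named dm were taken as spike-in and kept apart from the mouse peaks, which numbered 150680 to 193905 per library.

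Depth was read from the lists. With the form of fold and p that MACS2 uses, the pileup solved to a whole number within 0.1 in 100% of the 1016776 peaks, which gives the height of each summit in tags and the background of each library. The background was 1.09 and 1.18 tags in WT, 1.26 and 1.01 in KO, and 1.14 in both del-cIDR libraries. Dividing it by the narrowest peak of the list, on the assumption that this equals the fragment length used for calling, gave depths relative to WT replicate 1 of 1.10 for WT replicate 2, 1.10 and 0.820 for KO, and 0.975 and 0.959 for del-cIDR. Total reads per library are not analysed here. A region that is missing from a list may be open below the calling limit.

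Mouse peaks of all 6 libraries that overlapped by at least 1 bp were merged into 259376 regions, and each region was given a calling pattern over the libraries. The count of each genotype pattern was set against the count expected from a Rasch model, which has 1 detectability per library, 1 per region and no genotype term and was fitted by conditional maximum likelihood, and against the crossed patterns that take 1 library from each of the compared genotypes. For each number of libraries with a call, the expected counts add up to the observed total. An excess in genotype patterns therefore lowers the ratios of the crossed patterns, which are not a separate control. No p is given for single regions, because 2 against 2 libraries cannot give an exact two-sided p below 0.333. Chromosome classes were tested with an exact conditional test of a common odds ratio, two-sided, over 10 strata of peak strength. It set regions called in both libraries of one genotype and neither of the other against regions called in all 4, with Benjamini-Hochberg adjustment. Chromosome X was the planned class, adjusted over 6 comparisons; the other chromosomes were added after seeing the data, adjusted over all chromosomes and comparisons. Regions on one chromosome are not independent, so these p values are too small by an unknown amount.

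Heights were scaled inside each list. For 99146 regions called in all 6 libraries on assembled chromosomes, the log2 ratio of the median height of a chromosome to that of the 16 autosomes other than 6, 8 and 11 was taken in each library, and the ratios were then averaged by genotype. For bins and segments, each region's log2 height was taken relative to the median of the reference autosomes of its own list, the WT mean was subtracted, and the median over regions was used. This is another summary than the ratio of medians, and the distal X gives 0.39 with the one and 0.33 with the other. Segments were sought in bins of 1 Mb as the run of at least 5 bins that stood apart most, with 2000 shuffles of the bins. Their p compares positions along a chromosome, not replicates, and ignores the correlation of neighbouring bins. Clusters of genotype-specific regions were sought in windows of 1 Mb with an exact hypergeometric test. All of these height and window steps, and the choice of reference autosomes, were made after seeing the data. A limma test of recovered heights, region by region between libraries, was also run and its results were seen. It was left out, because the value of a peak describes that peak in its own list, and none of its results are given. Named regions are the 15 highest genotype-specific regions per comparison and direction, without scaffolds. They were ranked by the smaller of the within-list percentiles of fold in the libraries that have them. This ranking was fixed before the data were examined. The plan also divided the regions into those near genes and those elsewhere, which was dropped for lack of an annotation, so the rule used differs from the planned one.

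On simulated calls for KO against WT over 200000 regions, the model's ratio was 0.997 with no genotype effect. With 200 regions added, it recovered an excess of 152 regions. The exact test on 20000 simulated regions gave p at or below 0.05 in 4% of draws with an odds ratio of 1 and in 100% with an odds ratio of 2. The segment search on 120 bins passed 0.05 in 2% of draws without a shift and in 100% with a shift of 0.40. The simulated calls were drawn from the model itself, and the simulated regions and bins were independent of each other. These runs thus do not cover dependence between regions of a chromosome, correlation of neighbouring bins, or calls that depart from the model. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The alternatives tried were stricter limits on q, lists of equal length, other definitions of overlap, autosomes only, each library left out and pairing by replicate number. An annotation and a genome of build GRCm39 were not used here. The planned comparisons of promoters, the Alkbh5 gene, gene lists, sequence classes and motifs were therefore not run, and regions are given by position alone.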

Results

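ATAC-seq peaks were examined in mouse embryonic stem cells that carried wild-type Alkbh5, a knockout of Alkbh5, or the del-cIDR allele of Alkbh5, with 2 libraries per genotype. The mouse peak lists held 193905 and 184884 peaks in WT, 164639 and 150680 in KO, and 157931 and 155128 in del-cIDR. The means were 189394 ± 6379 for WT, 157660 ± 9871 for KO and 156530 ± 1982 for del-cIDR (SD, n = 2). Peaks covered 65.5 ± 2.06 Mb in WT, 59.7 ± 2.35 Mb in KO and 59.5 ± 0.139 Mb in del-cIDR (SD, n = 2). Both WT lists were longer than all 4 mutant lists, and list length was not tested. Of the 259376 merged regions, 99216 (38.3%) were called in all 6 libraries and 65303 (25.2%) in 1 library only. Libraries of one genotype shared 67.4% to 70.2% of their regions, and libraries of different genotypes 59.4% to 67.6%.

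The first comparison asks which regions were called in WT and not in KO, or in KO and not in WT. Each genotype may be a single line, so none of the comparisons separates the genotype from differences between lines. Both KO libraries lacked 18719 regions that both WT libraries had, which is 12.5% of the 150177 regions called in both WT libraries. In the other direction, 4910 regions were called in both KO libraries and neither WT library, 3.96% of the 123966 regions of KO. With the same number of peaks in every list the counts were 10577 and 9012, so most of the difference between the directions went with list length. In the full lists, both counts stood above those expected from library detectability alone. The ratio was 1.58 (2.29 at equal length) for the WT-specific and 2.25 (1.89 at equal length) for the KO-specific regions. Which direction had the larger ratio thus changed with list length. The crossed patterns of the same 4 libraries stood at 0.678 to 0.744 times in the full lists. Values below 1 there follow in part from the fit, which balances them against the genotype patterns. Of the KO-specific regions, 110 were at or above the median fold of both KO lists, and of the WT-specific regions, 1988 were at or above that of both WT lists. The crossed patterns held 37 to 127 such regions, a range that includes the 110 but is not corrected for the longer WT lists. With 1 library left out, and so fewer calls required, the KO-specific ratio was 1.55 without KO replicate 1, 1.26 without KO replicate 2, 1.297 without WT replicate 1 and 1.42 without WT replicate 2, and the WT-specific ratio was 1.13 to 1.31. With chromosomes 6, 8, 11 and X left out, an alternative chosen after seeing the data, 3213 KO-specific regions were 2.28 times the expected count.

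Chromosomes 6 and 8 stood apart in the KO cells. They held 6.89% ± 0.021 and 6.50% ± 0.0095 of the KO peaks, against 5.70% ± 0.0083 and 5.52% ± 0.034 in WT (SD, n = 2). KO-specific regions were enriched on chromosome 6 (odds ratio 2.47, 650 regions) and chromosome 8 (1.94, 546 regions), with exact stratified test adjusted p of 2.74e-66 and 2.64e-32. WT-specific regions were depleted there, with odds ratios of 0.42 and 0.45. Summits on chromosome 6 were 0.38 log2 higher relative to the reference autosomes in KO than in WT, at 0.29 ± 0.02 against -0.09 ± 0.01 on the log2 scale (SD, n = 2). Chromosome 8 was 0.33 log2 higher, at 0.41 ± 0.01 against 0.08 ± 0.01 (SD, n = 2). The 16 reference autosomes differed between KO and WT by -0.07 to 0.06 on the same scale. Chromosome 11 was raised over part of its length, from 11 to 56 Mb (GRCm39), where the 1878 regions called in all libraries differed from WT by 0.43 log2 and the remaining 5088 regions by 0.02. This segment had a permutation p of 0.0005, the smallest that the shuffles can give (adjusted p = 0.00666, Benjamini-Hochberg over 40 chromosome and genotype pairs). KO-specific regions on chromosome 11 as a whole had an odds ratio of 1.17 (exact p = 0.00675), which did not pass 0.05 with lists of equal length (odds ratio 1.09, exact p = 0.0527) or without KO replicate 1 (1.07), KO replicate 2 (1.04) or WT replicate 1 (1.06). On chromosome X, the class that was planned, KO-specific regions had an odds ratio of 0.97 (exact stratified test adjusted p = 0.859). WT-specific regions had one of 1.20 (adjusted p = 0.00633), a call that was lost without strata of strength (1.02, exact p = 0.677) and with lists of equal length (1.15, exact p = 0.0885).

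**Figure D1:**
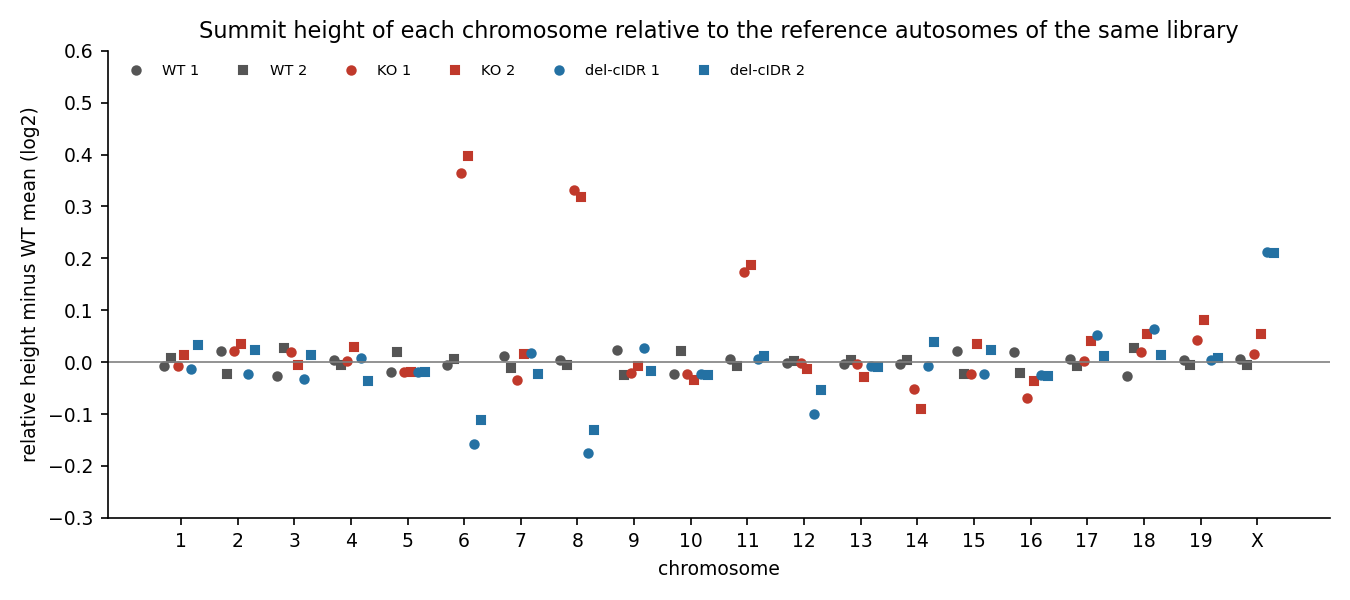
Median summit height of each chromosome relative to the 16 reference autosomes of the same library, minus the WT mean (log2), with circles for replicate 1 and squares for replicate 2. Both KO libraries lie above WT on chromosomes 6, 8 and 11, and both del-cIDR libraries lie above WT on chromosome X and below it on chromosomes 6 and 8.

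**Figure D2:**
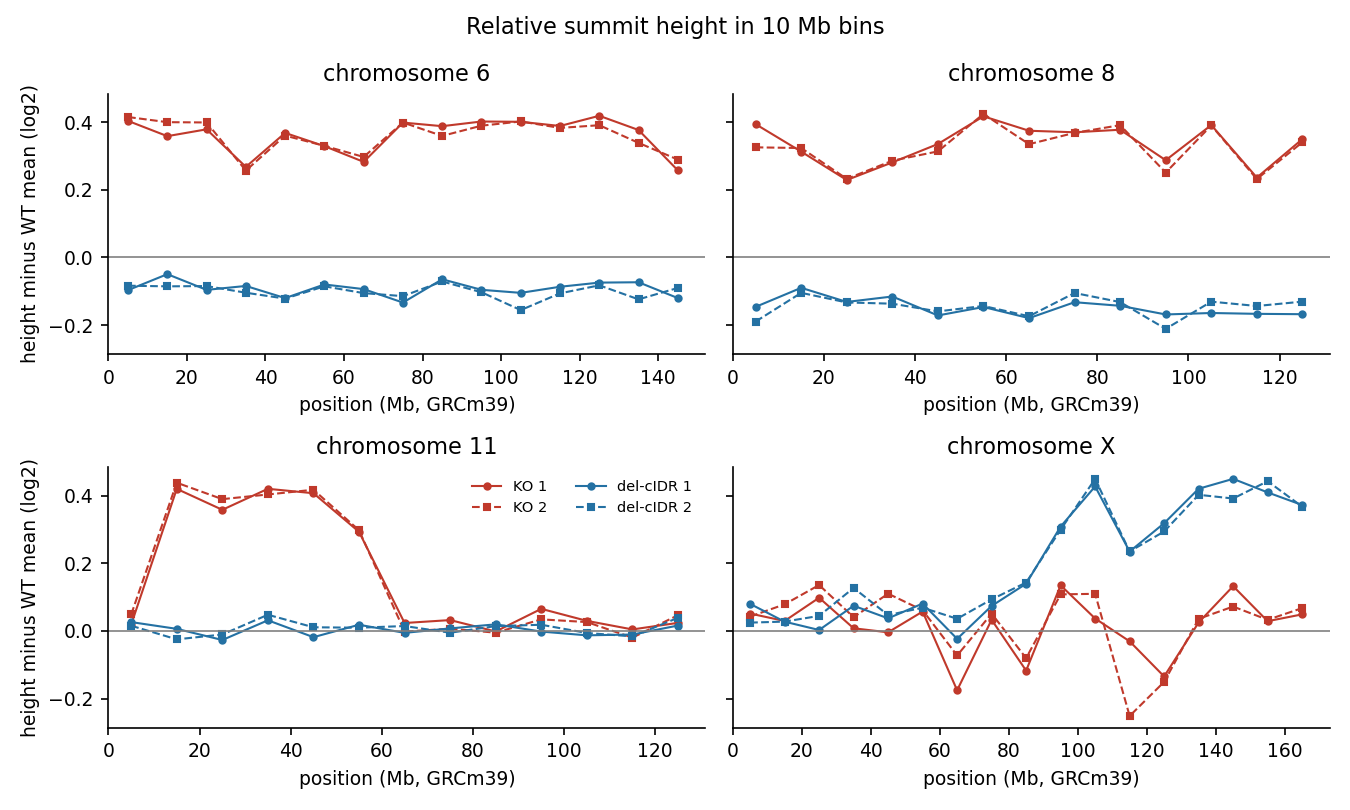
Height difference from the WT mean (log2) in bins of 10 Mb along chromosomes 6, 8, 11 and X, with 1 line per mutant library. KO is raised along chromosomes 6 and 8 (0.23 to 0.44 over their 28 bins) and from 10 to 60 Mb on chromosome 11. Del-cIDR is raised on the distal part of X.

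Among the 15 highest WT-specific regions against KO, 11 were also called in both del-cIDR libraries and 3 in no mutant library. Over all 18719, 5803 were called in both del-cIDR libraries and 6870 in none, so the highest regions do not stand for the whole list. The tallest, on chromosome 16 from 91331471 to 91331585, held 1175 and 1363 tags in the WT libraries and no call in the 4 mutant libraries. It was 115 bp wide, and the narrowest peaks of the WT lists were 114 and 113 bp. As merged regions, the named regions had a median width of 183 to 342 bp by direction. In 81 of the 90 named entries (69 distinct positions), the narrowest peak was under 250 bp. The median peak of a library was 270 to 310 bp wide. Regions in the top 1% of a library had a median width of 624 to 667 bp, and those of them that were missing from the replicate of the same genotype 173 to 307 bp. A region on chromosome 14 from 122151464 to 122151805 held 297 and 306 tags in WT and 273 and 268 in del-cIDR, and was not called in KO. The same pattern held on chromosome 5 from 135501279 to 135501508, with 223 and 225 tags in WT and 224 in each del-cIDR library. Chromosome 12 had WT-specific regions from 22186389 to 22186920 and from 23345358 to 23345630, both called in del-cIDR as well. Of the 15 highest KO-specific regions, 5 were called in KO alone, against 3078 of all 4910. The 5 include chromosome 17 from 29319193 to 29319589, with 127 and 120 tags, and chromosome 17 from 24198691 to 24198874, with 61 and 55 tags. A region on chromosome 8 from 74940946 to 74941267 reached 142 and 145 tags in KO and 14 in del-cIDR replicate 2.

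**Figure D3:**
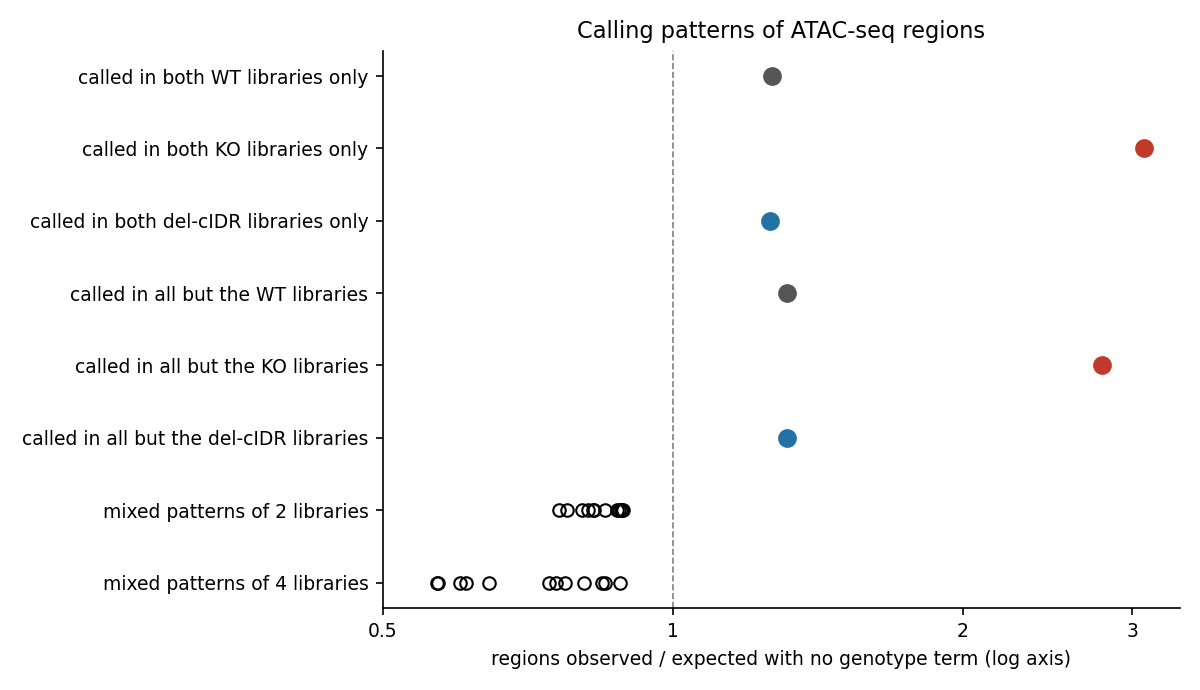
Number of regions with each calling pattern divided by the number expected with no genotype term (log axis). Filled points are patterns in which both libraries of each genotype behave alike, and open points are the 24 mixed patterns of 2 or 4 libraries. The KO patterns stand at 3.09 and 2.79, the other 4 genotype patterns at 1.26 to 1.32, and the mixed patterns at 0.569 to 0.888. The fit balances the mixed patterns against the genotype patterns, so their low ratios are not a separate control.

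The second comparison concerns the del-cIDR allele, in which ALKBH5 lacks the deleted part. Both WT libraries had 13817 regions that neither del-cIDR library had, 1.12 times the expected count. In the other direction, 2416 regions were called in both del-cIDR libraries and neither WT library, 1.15 times the expected count. With lists of equal length the counts were 6237 and 5647. The crossed patterns, which the fit balances against the genotype patterns, stood at 0.724 to 0.788 times in the full lists. At or above the median fold of both lists of their genotype were 865 of the WT-specific and 37 of the del-cIDR-specific regions, against 65 to 128 in the crossed patterns, again without correction for list length. Neither count kept a ratio above 1.03 when 1 of the 4 libraries was left out. The range was 0.957 to 1.03 for WT-specific and 0.851 to 0.979 for del-cIDR-specific regions, with fewer libraries required.

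Chromosome X held 2.34% ± 0.011 of the del-cIDR peaks against 2.09% ± 0.041 of the WT peaks (SD, n = 2). Of the regions specific to del-cIDR against WT, 112 lay on X (odds ratio 3.17, exact stratified test adjusted p = 6.69e-22), and WT-specific regions were depleted there (odds ratio 0.69, adjusted p = 3.25e-06). With 1 library left out, the odds ratio of the del-cIDR-specific regions was lower, at 1.96 to 2.69. Heights along X differed most on the distal part, from 92 to 169 Mb, where 1066 regions called in all libraries were 0.39 log2 above WT, while the remaining 1052 regions of X were 0.07 above. Of the 112 specific regions, 80 lay in this part and 32 outside, against 1355 and 1217 of the regions called in all 4 libraries (odds ratio 2.25, Fisher's exact test p = 9.44e-05, two-sided, chosen after seeing the data). The segment was defined by heights in these same libraries, and taller summits are called more often. This test, which has no strata of strength, is therefore not separate support for the segment. This segment had the smallest permutation p that the shuffles can give (0.0005, adjusted p = 0.00666). Chromosomes 6 and 8 went the other way in del-cIDR, with peak shares of 5.46% ± 0.046 and 5.22% ± 0.0076 (SD, n = 2), below WT. Regions specific to del-cIDR were depleted on chromosome 6 (odds ratio 0.68) and chromosome 8 (0.64), with exact stratified test adjusted p of 0.00077 and 0.00016. Summits on chromosomes 6 and 8 differed from WT by -0.13 and -0.15 log2. A distal segment of chromosome 12, from 52 to 120 Mb, differed by -0.12 log2 against 0.02 for the rest (permutation p = 0.0005, adjusted p = 0.00666).

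The highest del-cIDR-specific regions included chromosome 15 from 27517044 to 27517417, with 115 and 106 tags and no call in WT or KO, and X from 52093874 to 52094055, with 21 and 23 tags. A region on chromosome 9 from 37450533 to 37451049 was called in all 4 mutant libraries, with 53 and 49 tags in KO and 55 and 64 in del-cIDR, and in neither WT library. Among the 15 highest WT-specific regions against del-cIDR, 6 were called in both KO libraries, against 2933 of all 13817. One of them lies on chromosome 6 from 112948435 to 112948588, with 236 tags in both WT libraries and 211 and 208 in KO. There were 3 positions called in WT alone, against 6870 of all 13817, namely the chromosome 16 region above, chromosome 6 from 128326711 to 128326893 and chromosome 13 from 66711771 to 66711886.

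The third comparison sets the mutants against each other. Both del-cIDR libraries had 9301 regions that neither KO library had (1.92 times the expected count), and both KO libraries had 9075 that neither del-cIDR library had (1.75 times). The crossed patterns, which the fit balances against the genotype patterns, stood at 0.635 to 0.751 times. Of the 9301 regions missing in KO, 5803 were called in both WT libraries, and of the 9075 missing in del-cIDR, 2933 were. Regions specific to KO against del-cIDR were enriched on chromosome 6 (odds ratio 2.84, 1198 regions) and chromosome 8 (2.52, 1077 regions), with exact stratified test adjusted p of 3.51e-137 and 2.45e-101. Regions specific to del-cIDR were enriched on X (odds ratio 2.21, 323 regions, exact stratified test adjusted p = 2.72e-27), and those specific to KO were depleted there (0.63, adjusted p = 3.97e-06). Regions at or above the median fold numbered 767 for del-cIDR and 470 for KO. With 1 library left out, the ratio for del-cIDR-specific regions was 1.22 and 1.20 without del-cIDR replicates 1 and 2, and 1.46 and 1.37 without KO replicates 1 and 2. The ratio for KO-specific regions was 1.17 to 1.34. Without chromosomes 6, 8, 11 and X, 6003 regions specific to KO against del-cIDR were left. The highest del-cIDR-specific region was on chromosome 13 from 25517953 to 25518152, with 308 and 313 tags, and it was also called in WT replicate 2 with 321 tags.

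Regions shared by the mutants were fewer. All 4 mutant libraries and neither WT library had 503 regions, and both WT libraries and no mutant library had 6870. With lists of equal length the counts were 1660 and 2795. At full length, lists drawn independently from all 259376 merged regions would overlap in 45.7 and 997 regions. That baseline is too low, since both lists hold only regions absent from both WT libraries, or only regions present in both. Data simulated with no genotype effect on the full-length libraries gave 382 ± 18.7 and 5416 ± 65.5 regions (SD over 1000 simulated sets). These values stand against the 503 and 6870 observed. Because both mutants were compared with the same 2 WT libraries, which cannot be split with 2 in each part, an excess from those libraries is not separated from one shared by the mutants. Without WT replicate 1 or 2 the mutant-specific count was 0.759 and 0.910 times the expected one, and the WT-specific count was 0.948 and 1.04 times. Without 1 of the mutant libraries the ratios were 1.08 to 1.51 and 1.14 to 1.302. At or above the median fold there were 6 mutant-specific and 290 WT-specific regions.

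The spike-in gave 1679 and 1568 peaks in WT, 2082 and 1977 in KO and 1199 and 1104 in del-cIDR. At 511 spike-in regions called in all libraries, the median height relative to mouse regions of the same library was -1.39 ± 0.04 log2 in WT, -0.95 ± 0.08 in KO and -1.25 in both del-cIDR libraries (SD, n = 2). Spike-in regions were thus 1.36 times as high relative to mouse regions in KO as in WT, a difference of 0.44 log2. Both del-cIDR libraries also lay above both WT libraries, by 0.14 log2. The KO difference was 0.27 log2 and the del-cIDR difference 0.03 log2 for regions with a mean height of at least 20 tags, an alternative chosen after seeing the data.

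**Figure D4:**
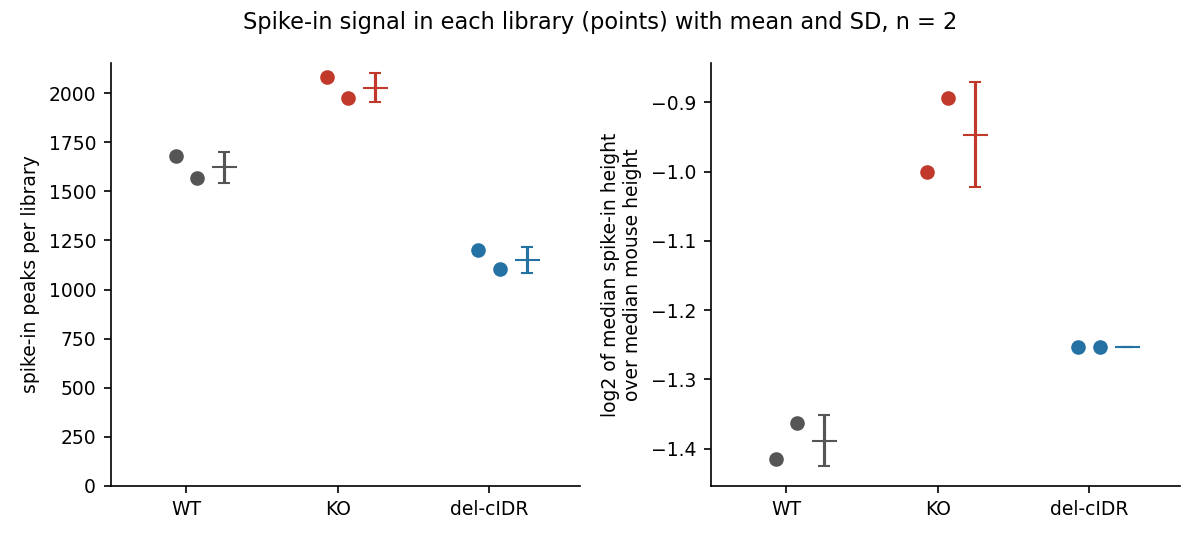
Spike-in peaks per library (left) and log2 of the median spike-in height over the median mouse height of the same library (right). Points are libraries, and bars show the mean and SD (n = 2). Both KO libraries lie above both WT libraries in each panel, and both del-cIDR libraries have the fewest spike-in peaks.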

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

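The tests in this part were chosen after the result was seen. The spike-in peaks, which the comparisons between genotypes do not use, numbered 2082 and 1977 in the KO libraries, above both WT libraries (1679 and 1568), while KO had 83.2% as many mouse peaks as WT. Lower depth of the KO libraries is argued against for the spike-in, since it would give fewer spike-in peaks and KO had 125% as many as WT. For the fewer mouse peaks it stays open, with a mean relative depth in KO of 91.4% of that of WT, although KO replicate 1, at 1.10, had fewer mouse peaks than both WT libraries. An unequal number of spike-in nuclei per cell could give the taller spike-in (0.44 log2 relative to mouse heights), and so could lower accessibility of the mouse genome in KO; these cannot be told apart because the number of nuclei was not analysed here. In del-cIDR, mouse peaks were 82.6% as many as in WT, spike-in peaks were fewer than in WT (1199 and 1104), and relative spike-in height was 0.14 log2 above WT (0.03 for regions of at least 20 tags).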

How the results depend on the processing

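The chromosome tests outside X, all relative heights and the setting without chromosomes 6, 8, 11 and X were chosen after seeing the data. Under stricter limits on q, equal list lengths, other overlaps, autosomes only and the last setting, each of the 8 counts stayed above the count expected without a genotype term, at 1.11 to 3.04 times. With the same number of peaks in every library, the counts became 9012 (KO not WT), 10577 (WT not KO), 5647 (del-cIDR not WT), 6237 (WT not del-cIDR), 1660 (all mutants not WT) and 2795 (WT only); the WT lists are shortened most, by construction. Regions in KO and not del-cIDR fell to 5954 at −log10 q of at least 5 and to 6003 without chromosomes 6, 8, 11 and X, where KO not WT gave 3213. Leaving out 1 library requires fewer calls and so raised every count. The ranges were 9029 to 18099 (KO not WT), 25576 to 43564 (WT not KO), 6067 to 11545 (del-cIDR not WT), 23357 to 39225 (WT not del-cIDR), 13915 to 23172 (del-cIDR not KO), 14963 to 27043 (KO not del-cIDR), 813 to 1903 (all mutants not WT) and 8252 to 26276 (WT only). Both del-cIDR counts against WT then lost their ratio above 1 or came within 0.03 of it, and without WT replicate 1 the ratio was 0.759 for all mutants and 0.948 for WT only (1.04 without WT replicate 2). The del-cIDR to WT ratio of peaks per library was 0.863 at −log10 q of at least 5, and over single libraries left out it was 0.807 to 0.847. The KO to WT ratio then was 0.796 to 0.869.

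Of 40 alternatives of the 5 tests of chromosome X with a call, 38 kept it, and KO not WT had no call under any of its 8; WT not KO (odds ratio 1.20) lost it without strata (1.02, exact p = 0.677) and with equal list lengths (1.15, exact p = 0.0885), and the cause was not tested. The odds ratio for del-cIDR not WT ranged from 1.96 to 4.04. Of 128 alternatives of the 16 tests of chromosomes 6, 8 and 11 with a call, 123 kept it, and the others concern chromosome 11 in KO not WT. Chromosome 11 in del-cIDR not WT had no call (0.91, exact p = 0.29) but gained one in 6 of 8 alternatives, at 0.83 to 0.88. In 448 of 449 cases a named region kept its pattern; with an overlap of 50% of the shorter peak, chromosome 1 from 5240657 did not, and chromosome 14 from 3051761 had no fixed window of its own and is not among the 449. The replicate block gives the same regions for the counts by construction (4910 for KO not WT). Differences in calls between replicates correlated by -0.013, 9.5e-05 and 0.0035 between genotypes, so the calls show no pairing by replicate number. The labels do not say whether libraries with the same number were prepared together, and these values cannot tell. With the replicate block the odds ratio of X was 2.04 for del-cIDR not WT, and chromosome 11 in KO not WT lost its call (1.03). A named region kept its pattern by construction when a library was left out, so this was not counted. Planned settings for promoters, gene lists and motifs, with their windows, were not run. Depth limits weak regions most: a missing call is not a closed region.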

Other observations

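The tests in this part were chosen after the result was seen. A segment of chromosome 15 from 15 to 21 Mb, with 49 regions, differed between del-cIDR and WT by -0.26 log2 (permutation p = 0.001, adjusted p = 0.01 over 40 pairs). The single del-cIDR libraries stood at -0.32 and -0.20. In KO, the search on this chromosome picked an overlapping segment from 18 to 23 Mb, at -0.21 log2 (permutation adjusted p = 0.261). Both mutants were set against the same WT libraries, so a difference in those libraries cannot be told apart from one in del-cIDR. The 39 regions of the Y chromosome stood at 1.37 ± 0.08 log2 above the reference autosomes in KO, against 0.71 ± 0.06 in WT and 0.98 ± 0.03 in del-cIDR (SD, n = 2). Clusters of genotype-specific regions were few, with 4 windows of 1 Mb past an adjusted p of 0.05 in exact hypergeometric tests of 14072. They were chromosome 11 from 47 to 48 Mb (11 of 30 KO regions absent from WT, exact test adjusted p = 0.00083), chromosome 4 from 133 to 134 Mb (25 of 147 KO regions absent from del-cIDR), chromosome 5 from 104 to 105 Mb (20 of 81 del-cIDR regions absent from KO) and chromosome 7 from 121 to 122 Mb (9 of 69 del-cIDR regions absent from WT). The window on chromosome 11 lies inside the segment raised in KO, from 11 to 56 Mb. Its test took the expectation from the whole chromosome, so the window is not separate from that segment. Tall regions were also absent between replicates: 5 to 17 of the 1507 to 1940 regions in the top 1% of a library were not called in its own replicate. The absent ones had a median width of 173 to 307 bp, against 624 to 667 bp for all regions in the top 1%. Named regions, at 183 to 342 bp by direction, were about as narrow as the absent ones.

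Chromosomes 6 and 8 were raised in both KO libraries. Sequencing depth is argued against, since the KO libraries differed in this shift by 2.34% of it over both chromosomes, 8.59% on chromosome 6 and 4.46% on chromosome 8, while their relative depths were 1.10 and 0.820. Regulation confined to part of these chromosomes, or to regions of some heights, is argued against too. All 28 bins were raised, by 0.23 to 0.44 log2, and the shift was 0.26 to 0.37 log2 in every decile of height. The run that stood apart most on chromosome 6, from 33 to 38 Mb, was 0.15 log2 above WT (permutation adjusted p = 0.261). Bins within chromosomes 6 and 8 spread 1.05 times as widely as bins on other autosomes. The latter spread includes differences between chromosomes, which lowers the ratio. These are medians over many regions, so regulation of scattered single regions was not tested. Extra copies of both chromosomes, a common event in cultured mouse stem cells for chromosome 8, may account for it. Of their bins, 89.3% (25 of 28) lay above all 213 reference bins, just under the bound of 90% for this test. A bin on chromosome 13 with 32 regions kept the share under that bound. The bound and the reference autosomes, which leave out chromosome 11, were set after seeing these heights, so this share decides nothing. Extra copies stay open, as copy number was not measured and each genotype may be a single line. A shift of 0.58 would be needed for 3 copies over 2 in all cells. That value takes WT to hold 2 copies in all cells, which was not measured either. Relative heights on chromosome 6 were -0.09 in WT, -0.22 in del-cIDR and 0.29 in KO. On chromosome 8 they were 0.08, -0.07 and 0.41, so the shift in KO is larger against del-cIDR than against WT.

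The distal X was raised in both del-cIDR libraries. An even change of the whole X chromosome is argued against, since the segment passed a permutation test that repeats the search for it (p = 0.0005, the smallest possible). That test ignores the correlation of neighbouring bins. The rest of X differed by 16.9% of the distal shift, a share that choosing the segment by these heights lowers. It was still 0.066 and 0.064 log2 above WT in the del-cIDR libraries. Extra copies of the distal part stay open. The 7 bins of 10 Mb that start within the segment, at 0.32 to 0.45 log2, all (100%) lay above all reference bins (highest 0.17). The bin from 90 to 100 Mb, which starts before the segment, stood at 0.30. The segment was chosen by these heights, so this decides nothing. The bin from 110 to 120 Mb, with 55 regions, stood at 0.23 and 0.24 in the single libraries. In a male line 2 copies over 1 in all cells would give 1 log2, so such copies, if there, could be in part of the cells only. Whether the allele itself changes X was not tested, since genotype and line cannot be separated in this design.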
